A study of Mus musculus with 20 samples.

How the data were processed

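Single eYFP-positive B cells and plasma cells were index-sorted from lymph nodes of C57BL/6 mice on day 15 of a primary response to NP-KLH, a hapten coupled to a carrier protein. The cells were taken 4 days after tamoxifen. Libraries followed FB5P-seq, a plate-based single-cell protocol that reads the 5' ends of transcripts and assembles the B cell receptor of each cell, with 22 cycles of preamplification per the labels. The 20 plates carry 2 sampleIDs, 10 plates with C57BL/6F and 10 with C57BL/6M. The letters F and M stand in a column named Sexe of the authors' table of cells, and the labels do not give the number of mice, so sex, the animal, the sampleID and anything handled apart between them cannot be separated. P-values measure the spread between plates only.

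The deposited matrix holds whole-number counts per gene and cell, for 16047 genes and 1367 cells. STAR 2.5.3a, HTSeq 0.9.1 and the mm10 build were used per the submitters' processing notes, which do not state how the cells were filtered. The highest deposited count per gene and cell was 4 to the power 5, the number of different molecular tags of 5 bases, and 95 cells held at least 1 gene at that ceiling, so abundant transcripts are compressed. The authors' table of cells gives the plate, the sort gate, a supervised annotation with 7 states, and a cell cycle phase. If the annotation was made from the same transcripts, its classes are not independent of the genes tested. Tests between annotated classes then describe the states. Its cell cycle columns are a score per cell with no fixed range in the deposited table, and only the phase was used here. The share of spike-in RNA is a fraction of the counts of each cell in the deposited values, although its column name says percent. The 10 index-sort fluorescence values are inverse hyperbolic sines of the signal divided by 10 or 100, as the deposited column names say. Heavy and light chain mutations are whole numbers of mutated bases per assembled chain in the deposited table, and the authors grouped heavy chains into clones by steps not stated in the labels.

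Plate totals ran from 5979 to 11908095 counts and from 10 to 78 cells. Plate 6 of C57BL/6F held 10 cells of 273 to 1460 counts each, and the other 19 plates held at least 3208858 counts. The median cell had 60536 counts (lowest 261, highest 736478) over 1425 genes (lowest 206, highest 5557). Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. A fold against a class with 0 counts of a gene was computed against a floor of 3 counts over all its pools together and is written as a fold against the floor. The floor covers counting error only. Where counts gather in few cells, a class of few or shallow cells can miss them, so such a fold is no lower limit.

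Counts were summed per plate and class, and a pool needed at least 5 cells. The annotated dark zone, light zone and light-to-dark zone cells formed the germinal centre B class, and the activated (prePC.Act) and memory-like (prePC.Mem) states formed the pre-plasma class. The 17 cells annotated pre-memory entered no class comparison. Each comparison was also run on the sort gates, in which the dark zone and light zone gates together formed the germinal centre gate. Pools were scaled by TMM, filtered by filterByExpr with the class as the group, and tested by edgeR 4.0.16 with estimateDisp, glmQLFit and glmQLFTest, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The plate was a block where most of the 20 plates held both classes. Only 9 plates held a pre-plasma and a germinal centre B pool and only 8 a plasma and a pre-plasma pool under the annotation, so those 2 comparisons were fitted as class plus sampleID, with 9 pre-plasma pools. The gate comparisons, plasma against germinal centre B and dark against light zone were fitted on 19 plates with the plate as block. The 2 pre-plasma states shared no plate with 5 cells of each and were compared on counts summed per sampleID, with the sampleID as block. C57BL/6M was compared with C57BL/6F within each class with no covariate.

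Standard errors were taken from the F statistic. A log2 fold change follows the fitted model, with the small prior count of edgeR, and the CPM values beside it are TMM-scaled means over pools with their SD. The fit itself and the filter by class were settled after numbers of called genes had been seen, the fit on simulated data with known changes. There, edgeR with estimateDisp gave between 0% and 5.26% false calls over 5 simulated designs, the fit without estimateDisp 17.1% to 26.5%, and DESeq2 11.8% to 51.7%. The same simulation recovered 19.4% to 46.2% of genes changed 4-fold and 1.04% to 14.8% of genes changed 2-fold, so small changes were mostly not detectable at this depth. It gave all pools of a design the same dispersion, whatever their number of cells. Its dispersions came from estimateDisp and it held no plate effect, which may favour the fit that was chosen. Germinal centre B draws of the size and depth of the pre-plasma pools were also set against other germinal centre B cells. They called a median of 743.5 genes with estimateDisp and 30 without it. The simulated rates therefore do not carry over to annotated pre-plasma against germinal centre B.

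Named genes followed a rule set before the data were examined. In each comparison it took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change, among those past the threshold. These needed an average logCPM of at least 5 and the same direction in both sampleIDs, and immunoglobulin segments and unnamed transcripts were left out. The rule added 13 fixed genes and the 3 members of each gene list with the smallest p. The text describes those that matter to each comparison. Results of some genes, and of a surface marker, are not reported here. The gene lists were fixed before the data were examined. They were plasma cell identity, ER protein folding and secretion, germinal centre B identity, light zone and activation, dark zone, Myc targets and ribosome biogenesis, S phase, G2 and M phase, B cell receptor signalling and B identity, MHC class II antigen presentation, migration and egress receptors, naive and memory B, immunoglobulin constant regions, oxidative phosphorylation, glycolysis, mitochondrial genome, immediate early and stress genes, and markers of T cells, of myeloid cells and of red and stromal cells.

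Lists with at least 3 tested genes were tested by camera of limma with a preset correlation of 0.01 on logCPM with a prior count of 2, which compares the list with all other genes. Camera with an estimated correlation was the alternative. Fry tested whether the genes of a list move, on balance, one way, and does not compare them with other genes. Members past the threshold are counted over all genes tested and adjusted over the list alone. List medians are plain medians of log2 fold changes, not set against the median of all genes, which was not 0. That median lay between -0.50 and -0.11 log2 in the gate comparisons and in plasma against germinal centre B. It is given with the lists of the other comparisons. Genes with near-identical copies, such as immunoglobulin constant and light chain genes and the MHC class II genes, can share reads in counting, and their values are uncertain to that extent.

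Median fluorescence and B cell receptor features per plate and class were compared by two-sided sign-flip permutation over plates with at least 5 cells of each class, exact under 10 plates and with 100000 resamples otherwise, with Benjamini-Hochberg adjustment over markers and comparisons. Mean mutations, the share of unmutated heavy chains and the share of IGHV1-72 were added to the receptor features after the data had been examined. Class shares per plate were compared between sampleIDs by permutation of plates. The constant region of a heavy chain was read from the deposited assembled sequence by matching its last 5 bases to the first 5 bases of the annotated constant regions, which did not separate IgG1, IgG2b and IgG2c. Clone sharing between classes was set against 10000 shuffles of the class labels within each sampleID, with clones counted apart in each sampleID.

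The alternatives chosen before the data were examined were DESeq2 1.42.0 with its own size factors, no filter on low counts, no immunoglobulin genes, at least 10 cells per pool, sums per sampleID, no plate block, each sampleID alone, cells thinned to equal counts, cells with at least 500 genes and under 20% mitochondrial counts, and the sort gate as class. For surface markers they were means of asinh(value / 150) and medians over all cells of each sampleID, and plate 6 left out and cells with at least 500 genes were added afterwards. Alternatives added afterwards were equal cell numbers, plate 6 left out, tag collisions corrected, the plate block on the plates with both classes, each pre-plasma state alone, at least 2 cells per plate and state, filterByExpr on the design, the fit without estimateDisp, each plate left out in turn, each of the 4 sums of the pre-plasma states left out in turn with no block, and C57BL/6F cells with Y-linked counts left out. Gene positions are those of GENCODE vM21 on GRCm38 (mm10). Computation used R 4.3.3, limma 3.58.1, Matrix 1.6.5, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The well-level names of cells and the light chain sequences were not used here.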

Results

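The data hold transcript counts, 10 index-sort fluorescence values and assembled B cell receptors for 1367 eYFP-positive cells from lymph nodes of immunised C57BL/6 mice. C57BL/6F contributed 626 cells on 10 plates and C57BL/6M 741 cells on 10 plates. The sort used 4 gates, with 325 cells in the dark zone gate, 367 in the light zone gate, 282 in the pre-plasma gate and 393 in the plasma cell gate. The authors' annotation names 7 states, with 452 dark zone, 278 light zone, 48 light-to-dark zone, 29 activated pre-plasma, 63 memory-like pre-plasma, 480 plasma and 17 pre-memory cells. Gate and annotation overlapped in part, since the pre-plasma gate held 128 cells annotated plasma, 63 dark zone, 29 activated, 27 memory-like, 23 light zone, 11 light-to-dark zone and 1 pre-memory. All 29 activated cells came from that gate, and 33 of the 63 memory-like cells came from the plasma cell gate. Depth differed between states, with a median of 3691 genes and 229914 counts in activated cells, 376 genes and 16638 counts in memory-like cells, 1510 genes in plasma cells and 1390.5 genes in germinal centre B cells. Values below are log2 fold changes with their SE and TMM-scaled CPM values with their SD over plates.

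Plasma cells were compared with germinal centre B cells to find the genes that part these classes, with 19 plates that held both. Fkbp11, an ER peptidyl-prolyl isomerase of secretory cells, rose by 12.13 ± 0.48 log2, from 0.697 ± 2.43 to 1452 ± 358 CPM (adjusted p = 1.11e-16). Sdc1, which encodes the plasma cell surface proteoglycan CD138, rose by 10.86 ± 0.51 log2 to 503 ± 132 CPM. Xbp1, a transcription factor of the secretory programme, rose by 4.21 ± 0.13 log2, from 212 ± 74.1 to 3739.6 ± 697 CPM (adjusted p = 1.29e-18). Prdm1, which encodes the plasma cell factor Blimp-1, rose by 8.39 ± 0.81 log2 and Irf4, which acts beside it, by 6.30 ± 0.70 log2. Tmem154 at 11.28 ± 0.57, the selenoprotein gene Selm at 11.02 ± 0.51, the glutathione peroxidase gene Gpx3 at 10.85 ± 0.45 and the surface antigen gene Ly6c2 at 10.69 ± 0.48 log2 were among those that rose most. The galectin gene Lgals1 rose by 2.24 ± 0.12 and Ccnd2, a G1 cyclin gene, by 5.56 ± 0.71 log2, and the inhibitor of DNA binding gene Id3 changed by -9.27 ± 0.67 log2. Bcl6, the main repressor of the germinal centre programme, changed by -8.06 ± 0.87 log2, and the B lineage factors Pax5 and Bach2 by -8.86 ± 0.74 and -9.29 ± 0.57 log2. Spib, another B lineage factor, fell by 10.30 ± 0.49 log2, and Sorl1 had 1 count in the plasma pools, a ratio of 3318 (counting interval 596 to 131052). Myc at -1.16 ± 0.75 log2 and Cxcr4 at -0.74 ± 0.68 log2 did not pass the test (adjusted p = 0.266 and 0.446). Over 7649 genes tested, edgeR called 2367, of which 1156 were higher and 1211 lower in plasma cells.

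All 20 tested members of the plasma cell identity list rose, with a median of 5.44 log2, among them Jchain, the joining chain of secreted IgM and IgA, at 2.12 ± 0.08 and the ER protein Mzb1 at 2.21 ± 0.08 log2. In the list of ER protein folding and secretion 31 of 33 members rose, led by the chaperone Hsp90b1 at 4.87 ± 0.10 log2, from 115 ± 28.2 to 3315 ± 506 CPM. Others were the signal peptidase subunit Sec11c at 3.18 ± 0.08 and the disulfide isomerase Pdia3 at 1.97 ± 0.05 log2. Immunoglobulin constant regions rose in 9 of 11 cases with 1 lower, with Ighg1 at 2.51 ± 0.14 and Iglc1 at 2.6 ± 0.10 log2. Germinal centre B identity fell in 17 of 18 members (median -4.52 log2), including Gcsam at -5.59 ± 0.66 and the confinement receptor S1pr2 at -5.72 ± 0.62 log2. Of 20 members of B cell receptor signalling and B identity 15 fell and 2 rose, with the inhibitory receptor Cd22 at -8.92 ± 0.73 and Ms4a1, which encodes CD20, at -2.88 ± 0.12 log2. MHC class II antigen presentation fell in 10 of 12 members with 1 higher, with the class II transactivator Ciita at -9.03 ± 0.60 and H2-Eb1 at -1.35 ± 0.07 log2. Light zone and activation genes fell in 10 of 20 with 1 higher, led by the activation marker Cd83 at -6.08 ± 0.62 log2, and dark zone genes in 6 of 13. Migration and egress receptors rose in 11 of 19 and fell in 3, with the egress receptor S1pr1 at 6.44 ± 1.18 log2 (adjusted p = 0.000131). Camera called these 9 lists, and each call held with an estimated correlation, at adjusted p from 1.73e-06 to 0.0437 with an estimated correlation. Adjusted over the list alone the counts were equal except 11 lower in light zone and activation.

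Among cell cycle genes, 14 of 23 S phase members fell with 1 higher (median -1.01 log2). Of 24 G2 and M phase members 12 fell (median -0.79 log2). Examples were the chromatin protein Hmgb2 at -1.54 ± 0.13, the histone mRNA binder Slbp at -1.10 ± 0.14 and the proliferation marker Mki67 at -0.51 ± 0.19 log2 (adjusted p = 0.0473). Oxidative phosphorylation genes rose in 9 of 19 with 1 lower, led by the ATP synthase subunit Atp5g1 at 1.46 ± 0.10 log2. These 3 list calls were lost, at adjusted p = 0.304, 0.367 and 0.146 with an estimated correlation. Lists that camera did not call were Myc targets and ribosome biogenesis (4 higher and 6 lower of 28, median -0.18 and mean 0.22 log2), naive and memory B (2 higher and 6 lower of 12) and glycolysis (5 lower of 13). It did not call the mitochondrial genome (1 higher and 3 lower of 7, mt-Cytb at -0.30 ± 0.06 log2) or immediate early and stress genes (3 higher and 1 lower of 8) either. The median of naive and memory B was -0.22 log2 and turned to 0.28 without immunoglobulin genes. Markers of other cell types were almost unmeasured, with 1 T cell gene, 1 myeloid gene and 2 red cell and stromal genes tested, which is under the 3 genes a list test needed. The sort gates gave 2398 called genes of 6865, 937 higher and 1461 lower in the plasma cell gate. There Fkbp11 stood at 13.12 ± 0.54, Sdc1 at 12.29 ± 0.42 and Xbp1 at 4.35 ± 0.14 log2, and Spib had 1 count in the plasma cell gate, a ratio of 4610 (827 to 182105). Of the annotated calls, 891 of the 1156 higher and 1033 of the 1211 lower genes were called in the same direction. In these gates camera called plasma cell identity (20 higher of 20, median 5.85), ER protein folding and secretion (31 higher of 33, median 3.0) and germinal centre B identity (16 lower of 17, median -4.91). Further gate calls were light zone and activation (1 higher and 14 lower of 19, median -3.21), dark zone (7 lower of 9, median -2.76) and B cell receptor signalling and B identity (2 higher and 15 lower of 20, median -2.27). The last were MHC class II antigen presentation (1 higher and 10 lower of 12, median -2.12), migration and egress receptors (9 higher and 2 lower of 15, median 2.11) and immunoglobulin constant regions (9 higher and 1 lower of 11, median 2.94). All held, at adjusted p from 1.48e-05 to 0.0208 with an estimated correlation. Camera also called S phase (17 lower of 23, median -1.92), G2 and M phase (13 lower of 24, median -1.62) and oxidative phosphorylation (8 higher and 1 lower of 19, median 0.13). These were lost, at adjusted p from 0.214 to 0.305 with an estimated correlation. It did not call Myc targets and ribosome biogenesis (4 higher and 8 lower of 27, median -0.50), naive and memory B (1 higher and 5 lower of 10, median -0.76) and glycolysis (6 lower of 13, median -0.76). It left uncalled mitochondrial genome (1 higher and 3 lower of 7, median -0.24) and immediate early and stress genes (3 higher and 1 lower of 7, median 0.24). Thinning of cells to equal counts moved the median of all genes in that gate comparison by -0.34 log2 and its split to 647 higher and 1724 lower.

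**Figure D1:**
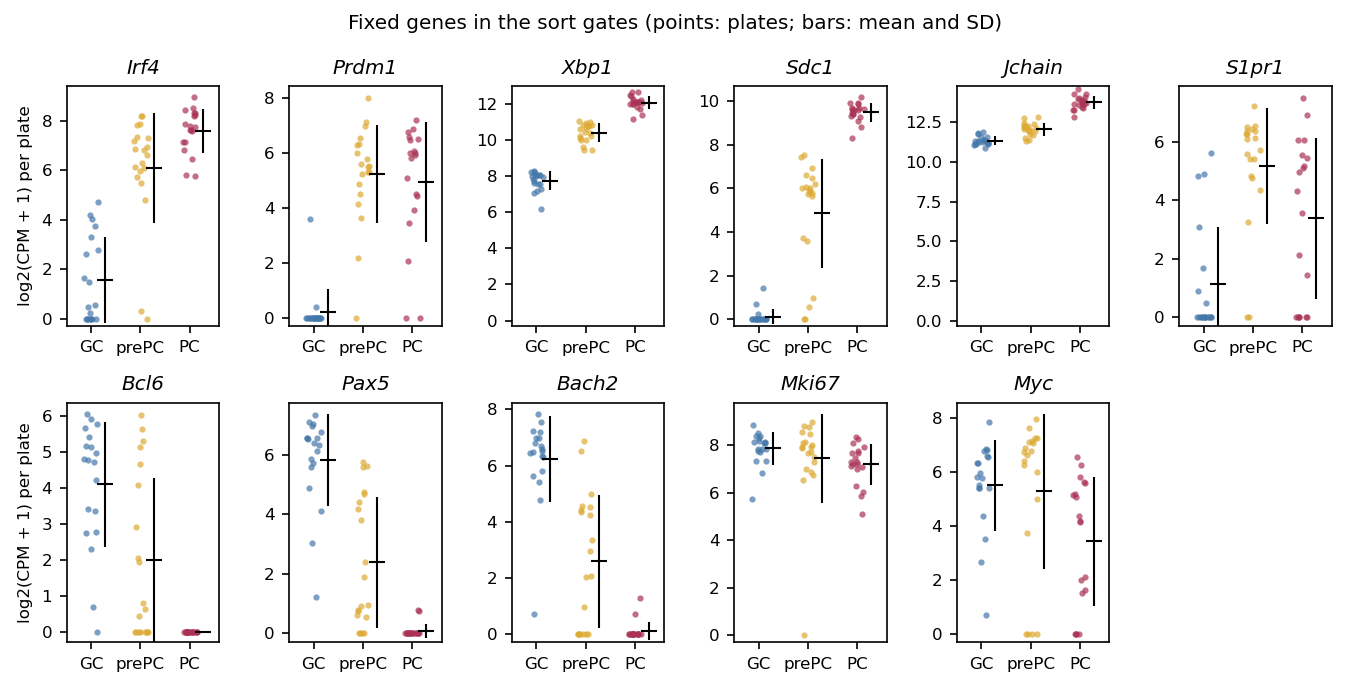
Expression of 11 genes in the germinal centre, pre-plasma and plasma cell gates, as log2 of CPM plus 1, with a point per plate and a cross for mean and SD. Xbp1, Sdc1 and Jchain are highest in the plasma cell gate, and Pax5 and Bach2 are lowest there.

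The pre-plasma gate was compared with the germinal centre gates to find the genes that differ between them, with 19 plates as blocks. Prdm1 rose by 9.07 ± 0.79 log2, from 0.616 ± 2.61 to 65.7 ± 59.6 CPM, Irf4 by 5.76 ± 0.80 and Xbp1 by 2.71 ± 0.17 log2, from 236 ± 69.1 to 1545 ± 452 CPM (adjusted p = 2.66e-12). The germinal centre and B lineage regulators fell, Bach2 at -4.04 ± 0.77, Pax5 at -3.73 ± 0.89 and Bcl6 at -3.13 ± 0.99 log2 (adjusted p = 0.0316). Tmem154, a transmembrane protein, had 0 counts in the germinal centre pools and 201 CPM in the pre-plasma gate, 2542-fold higher against the floor. Fkbp11 rose by 10.76 ± 0.53 and the ectonucleotidase gene Entpd1 by 10.23 ± 0.58 log2. Plac8 rose by 9.06 ± 0.87 and Prg2 by 8.88 ± 0.68 log2. The interleukin 4 receptor gene Il4ra at -5.20 ± 1.0, Fcer2a, which encodes CD23, at -3.85 ± 0.57 and Il4i1 at -3.80 ± 0.66 log2 were among the genes that fell most. Myc at 0.21 ± 0.70 and Mki67 at -0.04 ± 0.17 log2 did not pass the test (adjusted p = 0.896 and 0.933). Over 7150 genes edgeR called 1089, 507 higher and 582 lower, and 422 of the higher and 465 of the lower ones were called in the same direction between the plasma cell and germinal centre gates. Both comparisons used the same germinal centre gate pools, so part of this overlap is built in.

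In this gate comparison the secretory lists rose, with 14 of 15 plasma cell identity members and 30 of 33 ER members (median 2.71 and 1.91 log2). They include Hsp90b1 at 3.77 ± 0.14, Creld2 at 3.69 ± 0.20 and Manf at 2.75 ± 0.10 log2, which encode ER stress or folding proteins. Jchain rose by 0.67 ± 0.08 log2, and immunoglobulin constant regions rose in 7 of 11 with 1 lower. Migration and egress receptors rose in 9 of 18 and fell in 2, led by S1pr1 at 6.75 ± 1.07 log2. Germinal centre B identity fell in 17 of 19 members, among them Gcsam at -1.62 ± 0.17 log2. B cell receptor signalling and B identity fell in 12 of 20 with 1 higher, Ms4a1 at -1.85 ± 0.13 log2. MHC class II antigen presentation fell in 10 of 12, with the invariant chain Cd74 at -1.09 ± 0.07 log2. These 7 calls of camera held, at adjusted p from 0.000105 to 0.0337 with an estimated correlation. Camera also called light zone and activation (6 lower and 1 higher of 21) and the mitochondrial genome (4 lower of 7). Light zone members included Cd83 at -3.38 ± 0.28 and the cyclin gene Ccnd2 at 6.42 ± 0.76 log2. It called Myc targets as well (5 higher and 1 lower of 27, the spermidine synthase gene Srm at 3.4 ± 0.54 log2). None of these held, at adjusted p = 0.126, 0.0954 and 0.36 with an estimated correlation. The median of Myc targets, 0.23 log2, turned to -0.10 in cells thinned to equal counts. Camera did not call dark zone (3 lower of 13, median -0.59), naive and memory B (4 higher and 4 lower of 13, median -0.17) and oxidative phosphorylation (5 higher and 1 lower of 19, median 0.02). Nor did it call glycolysis (1 higher of 13, median 0.01) and immediate early and stress genes (1 higher of 7, median 0.36). Camera called neither S phase (1 higher and 1 lower of 23) nor G2 and M phase (2 higher and 2 lower of 24). The pre-plasma gate held 128 cells annotated plasma, so its higher plasma cell genes include those of that state.

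Under the annotation, 9 plates held at least 5 pre-plasma cells and were set against 20 germinal centre B pools. Xbp1 rose by 2.48 ± 0.25 log2 to 1407 ± 441 CPM, Fkbp11 by 7.99 ± 0.97, Irf4 by 4.11 ± 0.90, Hsp90b1 by 3.29 ± 0.28, Jchain by 1.40 ± 0.21 and the paraoxonase gene Pon3 by 4.46 ± 0.56 log2. Jchain was -0.56 log2 in the activated state alone (1819 CPM) and 3.14 log2 in the memory-like state alone (18219 CPM). Bach2 fell by 6.44 ± 0.98 log2, and Cd83 and Ms4a1 were lower by 4.92 ± 0.57 and 3.14 ± 0.42 log2. Rgs2, a regulator of G protein signalling, and the B lineage factor Ebf1 had 0 counts in the pre-plasma pools, 255-fold and 103-fold lower against the floor. Gsn, which encodes the actin-severing protein gelsolin, had 1 count there, a ratio of 1311 (235 to 51772). Bcl6 also had 1 count, a ratio of 186 (counting interval 33.4 to 7361), and Pax5 had 2, a ratio of 223 (61.8 to 1844). These intervals and the folds against the floor cover counting error only, not the spread between cells. The pools left out activated cells of plates with fewer than 5 pre-plasma cells. Over all 29 activated cells Pax5 had 57 counts, in 17.2% of cells at 7.49 CPM, against 104 CPM in dark zone and 44.1 in light zone cells. Memory-like cells had 0 CPM of Pax5. Myc was 0.61 ± 0.68 and Mki67 -0.11 ± 0.37 log2, both short of the threshold. Of 7942 genes tested 1433 were called, 170 higher and 1263 lower, and 144 of the 170 higher but 397 of the 1263 lower genes were called in the same direction in the gates. Germinal centre B pools drawn at the same cell numbers and genes per cell, set against the other germinal centre B cells of their plates, called a median of 743.5 genes over 20 draws, 99.8% of them lower (highest draw 847). Draws matched on cell numbers only called a median of 687 genes, and the highest 1228. Cd83 was lower in 10 and Ms4a1 in 6 of the 20 draws matched on both. Without estimateDisp the draws called a median of 30 (1 to 150) and the real comparison 307 higher and 894 lower. The plate block on the plates with both classes gave 42 higher and 135 lower, and equal cell numbers 26 higher and 18 lower.

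Plasma cell identity (8 higher of 13), ER protein folding (25 higher of 33), immunoglobulin constant regions (8 higher and 1 lower of 12, Ighg2c at 4.05 ± 0.39 log2) and germinal centre B identity (17 lower of 19) were called in the annotated comparison. These 4 held, at adjusted p from 2.32e-05 to 0.0114 with an estimated correlation. Light zone (8 lower and 1 higher of 22), dark zone (5 lower of 13), and B cell receptor genes (14 lower of 20) were called by camera as well. So were Myc targets (2 higher of 27) and oxidative phosphorylation (2 higher of 19, median -0.18 log2, camera direction up). These 5 were lost, at adjusted p from 0.218 to 0.422 with an estimated correlation. Camera did not call S phase (2 lower of 23, median -0.30), G2 and M phase (2 lower of 24, median -0.44) and MHC class II antigen presentation (10 lower of 12, median -1.30). Nor did it call migration and egress receptors (2 higher and 3 lower of 16, median 0.29), naive and memory B (4 lower of 15, median -0.91) and glycolysis (0 past the threshold of 13, median -0.15). The last were mitochondrial genome (2 lower of 7, median -0.49) and immediate early and stress genes (0 past the threshold of 6, median -0.42). The median of all genes was -0.71 log2 in this comparison, below that of oxidative phosphorylation, and the DESeq2 size factors moved it by 0.25 log2.

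The plasma cell gate was compared with the pre-plasma gate on 19 plates. Xbp1 rose by 1.59 ± 0.10 log2, from 1486 ± 445 to 4401 ± 1052 CPM, Sdc1 by 4.07 ± 0.49, from 64.2 ± 52.5 to 725 ± 181 CPM, and Jchain by 1.70 ± 0.07 log2 (adjusted p = 1.58e-14). The prolactin receptor gene Prlr at 7.25 ± 1.02, the autophagy gene Wipi1 at 6.55 ± 1.0, Cd93 at 5.77 ± 1.04 and Cd28 at 5.62 ± 0.90 log2, which both encode surface receptors of plasma cells, were among the genes that rose most. The pre-plasma gate held 63 cells annotated dark zone, 23 light zone and 11 light-to-dark zone. Germinal centre transcripts were lower in the plasma cell gate, where Gcsam fell by 9.31 ± 0.76, the follicle homing receptor Cxcr5 by 8.82 ± 0.93, Rgs13 by 8.59 ± 0.87 and Cd22 by 7.19 ± 1.06 log2. Spib had 1 count in the plasma cell gate, a ratio of 1086 (195 to 42901). Myc fell by 2.5 ± 0.78 and Mki67 by 0.67 ± 0.21 log2 (adjusted p = 0.0262 and 0.0272). Irf4 at 0.99 ± 0.41, Prdm1 at -0.67 ± 0.54 and S1pr1 at -2.22 ± 0.98 log2 did not pass the test (adjusted p = 0.103, 0.457 and 0.128), so no further change of these regulators was detectable at this depth. Of 6564 genes 1189 were called, 553 higher and 636 lower.

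Plasma cell identity rose in 17 of 20 members (Mzb1 at 1.26 ± 0.08 log2) and ER protein folding in 27 of 33 (Ssr4 at 1.83 ± 0.10, Spcs1 at 1.60 ± 0.09 log2, both of the translocation machinery). Immunoglobulin constant regions rose in 7 of 10 (Igkc at 1.46 ± 0.07, Ighg1 at 2.58 ± 0.20 log2). Germinal centre B identity fell in 8 of 14 members and dark zone genes in 7 of 10, and these 5 calls held at adjusted p from 0.000494 to 0.0128 with an estimated correlation. Annotated plasma against pre-plasma cells gave no such falls, with 0 lower of 12 for germinal centre B identity (median 0.71 log2), 0 of 11 for dark zone, 0 of 23 for S phase and 0 of 24 for G2 and M phase. Only 14 of all 7451 genes were lower there, and the median of all genes was 0.65 log2. The absence of falls therefore does not set these lists apart from other genes. In the gates S phase fell in 17 of 23 members (21 adjusted over the list alone) and G2 and M phase in 18 of 24 (23 adjusted over the list alone). Among them were the replication helicase gene Mcm4 at -2.84 ± 0.51, Hmgb2 at -2.11 ± 0.25 and the cyclin gene Ccnb2 at -1.81 ± 0.37 log2. Those 2 calls were lost, at adjusted p = 0.0959 for each with an estimated correlation. Glycolysis (7 lower of 13, Gapdh at -1.29 ± 0.18 log2), light zone (7 lower of 17), B cell receptor genes (10 lower and 2 higher of 18), and MHC class II (8 lower and 2 higher of 12, H2-Aa at -1.29 ± 0.16 log2) were also called by camera. So were Myc targets (7 lower and 3 higher of 28) and the mitochondrial genome (3 higher of 7, mt-Co1 at 0.76 ± 0.07 and mt-Cytb at 0.59 ± 0.07 log2). All 6 were lost, at adjusted p from 0.0802 to 0.288 with an estimated correlation. Migration and egress receptors were mixed, 7 higher and 3 lower of 17 (4 higher and 5 lower with equal cell numbers), and were not called. Also not called were naive and memory B (1 higher and 3 lower of 8, median -1.51), oxidative phosphorylation (4 higher and 1 lower of 19, median 0.10) and immediate early and stress genes (2 higher and 1 lower of 7, median 0.70).

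Annotated plasma cells (19 pools) against annotated pre-plasma cells (9 pools) gave 793 called genes of 7451, 779 higher and 14 lower. Xbp1 rose by 1.58 ± 0.17, Sdc1 by 4.18 ± 0.71, the ER degradation factor Derl3 by 3.01 ± 0.37 and the chaperone Hspa5 by 1.22 ± 0.13 log2. Insl6 and Wipi1 had 0 counts in the pre-plasma pools and were 155-fold and 111-fold higher in plasma cells against the floor. The genes that fell included Nhp2 of ribosome biogenesis at -1.31 ± 0.30 and the mitochondrial chaperonin Hspe1 at -1.04 ± 0.26 log2. Jchain at 0.67 ± 0.25, Irf4 at 0.89 ± 0.54 and Prdm1 at 1.59 ± 0.85 log2 did not pass. Plasma cell identity rose in 13 of 20 members (adjusted p = 0.0371 with an estimated correlation), and ER protein folding in 27 of 33 (adjusted p = 0.21 with an estimated correlation, where the camera call was lost). Camera also called, with direction down, light zone and activation (1 higher of 17, median -0.03), Myc targets and ribosome biogenesis (1 higher and 2 lower of 28, median -0.38) and S phase (0 past the threshold of 23, median -0.32). Down too went the calls for G2 and M phase (0 past the threshold of 24, median -0.24), MHC class II antigen presentation (1 higher and 1 lower of 11, median 0.11) and oxidative phosphorylation (1 higher of 19, median 0.29). Each was lost, at adjusted p from 0.261 to 0.54 with an estimated correlation. The medians of MHC class II and oxidative phosphorylation and the mean of light zone were above 0 there. The median of all genes was 0.65 log2, and camera compares a list with all other genes. Not called were germinal centre B identity (1 higher of 12, median 0.71), dark zone (0 past the threshold of 11, median -0.21) and B cell receptor signalling and B identity (3 higher of 16, median 0.65). Further uncalled lists were migration and egress receptors (3 higher of 20, median 0.66), naive and memory B (0 past the threshold of 11, median 0.56) and immunoglobulin constant regions (4 higher of 10, median 0.82). The last were glycolysis (0 past the threshold of 14, median 0.19), mitochondrial genome (1 higher of 7, median 0.27) and immediate early and stress genes (2 higher of 9, median 2.07). The number of calls fell to 15 at equal cell numbers, all higher, and to 92 with the plate as block on the 8 shared plates, all higher. DESeq2 size factors moved the median of all genes by -0.46 log2 and gave 679 higher and 166 lower, and thinning moved it by 0.20.

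**Figure D2:**
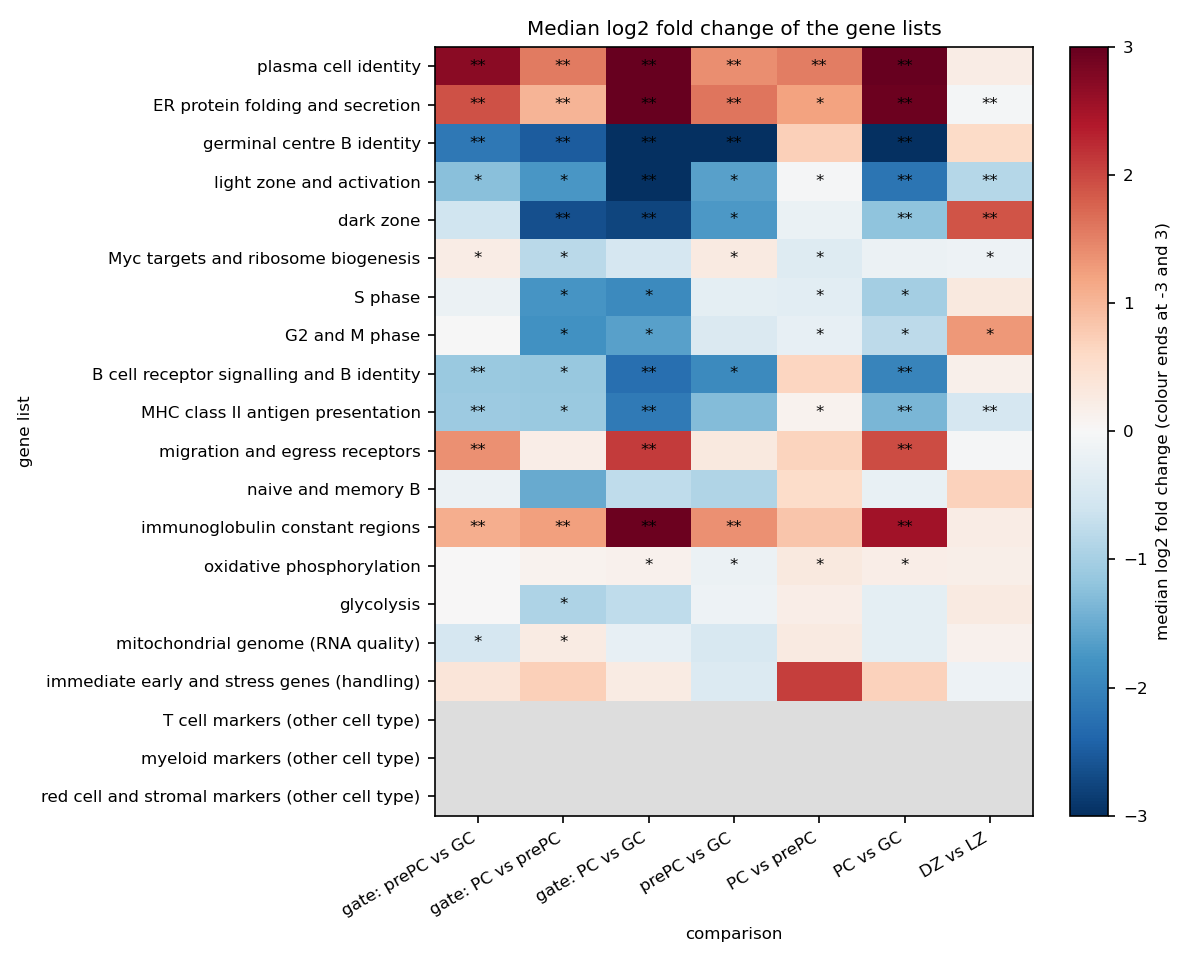
Median log2 fold change of each gene list (lists in lines, comparisons in columns, colour scale ending at -3 and 3). A star marks an adjusted camera p under 0.05, 2 stars one that also holds with an estimated correlation, and grey too few genes, and plasma cell identity is higher between the gates of germinal centre and pre-plasma cells (median 2.71) and again between those of pre-plasma and plasma cells (median 1.55).

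Dark zone cells were compared with light zone cells to describe the 2 germinal centre compartments on 19 plates. Dark zone cells had higher Gcsam at 1.88 ± 0.22, the base excision repair gene Neil1 at 1.60 ± 0.18, Hmces at 1.78 ± 0.24 and the translesion polymerase gene Polh at 5.28 ± 1.20 log2. The mitotic genes Ccnb2 at 1.99 ± 0.34 and Cdc20 at 1.93 ± 0.41 log2 rose, as did Rgcc at 3.4 ± 0.79, Pafah1b3 at 2.62 ± 0.43 and Mbd2 at 4.29 ± 0.74 log2. Jchain at 0.58 ± 0.10 and Mzb1 at 0.61 ± 0.10 log2 were also higher. In the sort gates Cdc20 was -0.18 and Mki67 -0.41 log2, and the median of G2 and M phase -0.34, against 1.30 under the annotation. Light zone cells had higher Cd83, which changed by -1.83 ± 0.10 log2 (adjusted p = 2.99e-13), Il4i1 at -2.32 ± 0.45, the NF-kappa-B inhibitor gene Nfkbia at -1.74 ± 0.28, Fcer2a at -1.53 ± 0.29, Cd72 at -1.66 ± 0.31 and Hspa5 at -0.82 ± 0.11 log2. Bcl6 at 2.37 ± 1.11 and Mki67 at 0.89 ± 0.38 log2 did not pass (adjusted p = 0.432 and 0.355). Dark zone genes rose in 4 of 10 members (7 adjusted over the list alone). Light zone genes fell in 3 of 18 (5 adjusted over the list alone, with 1 higher). MHC class II antigen presentation fell in 7 of 12 (H2-Ab1 at -0.51 ± 0.05, H2-Aa at -0.56 ± 0.06 log2). Each of these 3 calls held, at adjusted p = 0.000276 with an estimated correlation. ER protein folding, with 1 lower of 32 and a median of -0.06 log2, was called lower relative to other genes (adjusted p = 0.00228 with an estimated correlation). G2 and M phase, with 4 higher of 24 and 14 adjusted over the list alone, and Myc targets (0 of 24 past the threshold) were called by camera and lost, at adjusted p = 0.124 and 0.13 with an estimated correlation.

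Between the zones camera did not call plasma cell identity (2 higher of 9, median 0.22), germinal centre B identity (5 higher of 19, median 0.57) and S phase (0 past the threshold of 23, median 0.29). Likewise uncalled were B cell receptor signalling and B identity (2 lower of 20, median 0.15), migration and egress receptors (0 past the threshold of 9, median -0.04) and naive and memory B (1 lower of 7, median 0.68). To these came immunoglobulin constant regions (0 past the threshold of 11, median 0.23), oxidative phosphorylation (1 higher of 19, median 0.17) and glycolysis (0 past the threshold of 12, median 0.27). The last were mitochondrial genome (0 past the threshold of 7, median 0.14) and immediate early and stress genes (0 past the threshold of 5, median -0.16). The median of all genes between the annotated zones was 0.44 log2. Of 5447 genes tested between the zones 77 were called, 46 higher and 31 lower in the dark zone, and DESeq2 called 569 (458 higher, 111 lower), but counts summed per sampleID gave 1 call, lower. The sort gates called 18 of 5904, 11 higher and 7 lower, of which 10 and 6 were called in the same direction under the annotation. They included Rgcc at 1.78 ± 0.28, Pafah1b3 at 1.52 ± 0.20, Hmces at 0.93 ± 0.14, Gcsam at 0.79 ± 0.16, Jchain at 0.54 ± 0.08, Il4i1 at -2.59 ± 0.40, Cd83 at -1.13 ± 0.14, Cd52 at -0.43 ± 0.07 and H2-Eb1 at -0.39 ± 0.08 log2. The gate medians of all genes moved by under 0.1 log2 with scaling, and light zone genes were lower there, 2 of 19 over all genes and 7 adjusted over the list alone (adjusted p = 0.000121 with an estimated correlation). In the gates camera also called plasma cell identity (1 higher of 10, median 0.32), germinal centre B identity (2 higher of 19, median 0.19) and dark zone (1 higher of 9, median 0.32). Its calls also took in Myc targets and ribosome biogenesis (0 past the threshold of 24, median -0.32), G2 and M phase (0 past the threshold of 24, median -0.34) and B cell receptor signalling and B identity (0 past the threshold of 20, median 0.19). The last were MHC class II antigen presentation (2 lower of 12, median -0.29), immunoglobulin constant regions (0 past the threshold of 11, median 0.48) and immediate early and stress genes (0 past the threshold of 5, median -0.83). Each was lost, at adjusted p from 0.0596 to 0.514 with an estimated correlation. The gates gave no call for ER protein folding and secretion (0 past the threshold of 32, median -0.10), S phase (0 past the threshold of 23, median -0.05) and migration and egress receptors (0 past the threshold of 9, median -0.26). They gave none for naive and memory B (0 past the threshold of 7, median 0.27), oxidative phosphorylation (0 past the threshold of 19, median 0.04) and glycolysis (0 past the threshold of 12, median -0.01). The last were mitochondrial genome (0 past the threshold of 7, median -0.06).

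The activated and memory-like pre-plasma states were compared on 2 sums each, of 29 and 63 cells. Memory-like cells had more Apoe, which encodes the lipid carrier apolipoprotein E, at 3856 ± 339 against 8.52 ± 5.75 CPM (-8.97 ± 0.49 log2, activated against memory-like). They also had more Jchain (-3.69 ± 0.24), Ighm (-4.03 ± 0.35), Igkc (-3.06 ± 0.24), Ssr4 (-2.51 ± 0.37), Cd74 (-1.93 ± 0.26) and mt-Cytb (-2.35 ± 0.25). Prg2 and Isg20 were also lower in activated cells, at -5.55 ± 0.60 and -4.13 ± 0.53 log2. Activated cells had more of the purine synthesis gene Adsl and the RNA binding protein gene Ilf2, 131-fold and 109-fold against the floor, with 0 counts in memory-like cells. The mitotic kinase gene Aurka had 2 counts in memory-like cells, a ratio of 201 (55.8 to 1664). The chaperone partner Fkbp4 rose by 5.12 ± 1.08, the replication gene Mcm5 by 3.29 ± 0.93 and the mitotic gene Ube2c by 3.99 ± 1.07 log2. Mki67 at -0.70 ± 0.66 log2 did not pass (adjusted p = 0.886), and no order was read for it, since it was found in 79.3% of thinned activated cells (60.3 to 92.0, 309 CPM) and 19.5% of thinned memory-like cells (8.82 to 34.9, 463 CPM). By the deposited phase 51.7% of activated and 7.94% of memory-like cells were in G2 and M. Of 7186 genes 128 were called, 21 higher and 107 lower in activated cells, on 4 sums with 1 residual degree of freedom. The split turned to 176 higher and 11 lower on plates with at least 2 cells of each state and the plate as block. All 21 higher calls were lost when the activated sum of either sampleID was left out. Without the memory-like sum of C57BL/6F the split was 368 higher and 183 lower, and without that of C57BL/6M 1314 and 527. Thinning to equal counts moved the median of all genes by 0.16 log2. Immunoglobulin constant regions (8 lower of 11), plasma cell identity (7 lower of 20), ER protein folding (8 lower of 33), and MHC class II (3 lower of 12) were called by camera. So were the mitochondrial genome (2 lower of 7), B cell receptor genes (2 lower of 20), oxidative phosphorylation (1 lower of 19) and germinal centre B identity (0 of 14). None held, at adjusted p = 0.526 for each with an estimated correlation. No call was made for light zone and activation (0 past the threshold of 18, median 0.93), dark zone (0 past the threshold of 11, median 1.23) and Myc targets and ribosome biogenesis (0 past the threshold of 28, median 1.38). None was made for S phase (1 higher of 23, median 1.84), G2 and M phase (2 higher of 24, median 1.54) and migration and egress receptors (0 past the threshold of 23, median 3.12). The last were naive and memory B (0 past the threshold of 14, median 0.89), glycolysis (0 past the threshold of 14, median 2.01) and immediate early and stress genes (0 past the threshold of 7, median 0.15). The migration median is 2.21 when folds against the floor replace fitted ones. The median of all genes between these sums was 1.28 log2, so list medians near or below it show no rise relative to other genes.

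Irf4 was detected, with each cell thinned to 10000 counts, in 58.6% of activated cells (38.9 to 76.5, 62.1% unthinned, 186 CPM), 7.32% of memory-like cells (1.54 to 19.9, 6.35% unthinned, 123 CPM) and 35.4% of plasma cells (31.1 to 39.9, 42.3% unthinned, 188 CPM). It was found in 1.64% of light zone cells (0.448 to 4.14, 3.24% unthinned, 9.39 CPM) and 10.4% of light-to-dark zone cells (3.47 to 22.7, 14.6% unthinned, 10.8 CPM). Xbp1 was detected, with each cell thinned to 10000 counts, in 93.1% of activated cells (77.2 to 99.2, 93.1% unthinned, 879 CPM), 80.5% of memory-like cells (65.1 to 91.2, 84.1% unthinned, 2130.3 CPM) and 98.5% of plasma cells (97.0 to 99.4, 99.2% unthinned, 3359.8 CPM). It was found in 32.4% of light zone cells (26.5 to 38.6, 37.1% unthinned, 227 CPM) and 66.7% of light-to-dark zone cells (51.6 to 79.6, 81.2% unthinned, 234 CPM). Shallower cells were left out, 37 dark zone, 34 light zone, 0 light-to-dark zone, 0 activated, 22 memory-like, 3 plasma. No order was read for Irf4 between activated and plasma cells or for Xbp1 between activated and memory-like cells, where the share and the CPM run in opposite directions (Xbp1 was -1.58 ± 0.37 log2 between the sums).

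Surface markers followed the classes on 19 plates. These markers were used in the sort, and 73.1% of annotated plasma cells came from the plasma cell gate. Percentile 10 of CD138 was 3.37 in that gate, and its percentile 90 was 2.25 in the pre-plasma gate. The differences were thus set in part by the sort, and their p-values are no independent support for the classes. Plasma cells against germinal centre B cells had CD138 higher by 3.74 (SD 0.186), PSGL1 higher by 2.20 (SD 0.159) and the chemokine receptor CXCR4 higher by 0.596 (SD 0.210). They had the germinal centre marker GL7 lower by a difference of -2.0 (SD 0.442), B220 at -1.11 (SD 0.225) and CD86 at -1.11 (SD 0.216). Each showed its direction on 19 of 19 plates, at a permutation p of 1e-05, the smallest that 100000 resamples give (adjusted p = 4.44e-05). The viability dye was also higher in plasma cells, by 0.779 (SD 0.202) on 19 of 19 plates, with the same p. CD38 was higher by 0.103 (13 of 19 plates, permutation adjusted p = 0.0137), but did not pass with means of asinh(value / 150), at 0.0416 (12 of 19 plates, permutation adjusted p = 0.335), or in cells with at least 500 genes (permutation adjusted p = 0.059). The combined Gr1, CD3 and IgD stain was lower at -0.207 (17 of 19 plates, permutation adjusted p = 0.000655). Annotated pre-plasma cells had CD138 at 2.01 and PSGL1 at 1.61 above germinal centre B cells (9 of 9 plates each, exact permutation adjusted p = 0.0112), B220 at -0.537 and CD86 at -0.815 (8 of 9 plates, exact adjusted p = 0.0247). CD38 was 0.310 above germinal centre B cells (8 of 9 plates, exact adjusted p = 0.335), and without plate 6 0.561 above (8 of 8 plates, exact adjusted p = 0.0174). Plasma cells exceeded pre-plasma cells in CD138 by 1.76 and PSGL1 by 0.607 (7 of 8 plates, exact adjusted p = 0.0298). They had lower CD38 at -0.450 (8 of 8 plates, exact adjusted p = 0.0184) and B220 at -0.579 (7 of 8 plates, exact adjusted p = 0.0426). Dark zone cells had higher CXCR4 than light zone cells by 0.544 (19 of 19 plates, permutation adjusted p = 4.44e-05), GL7 by 0.450 (14 of 19, 0.0184) and CD138 by 0.139 (16 of 19, 0.00723), and lower CD86 at -0.589 (17 of 19, 0.000655). The CD138 difference between the zones did not pass with means of asinh(value / 150), at 0.0389 (13 of 19 plates, permutation adjusted p = 0.335). Of 40 marker tests 18 did not pass.

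**Figure D3:**
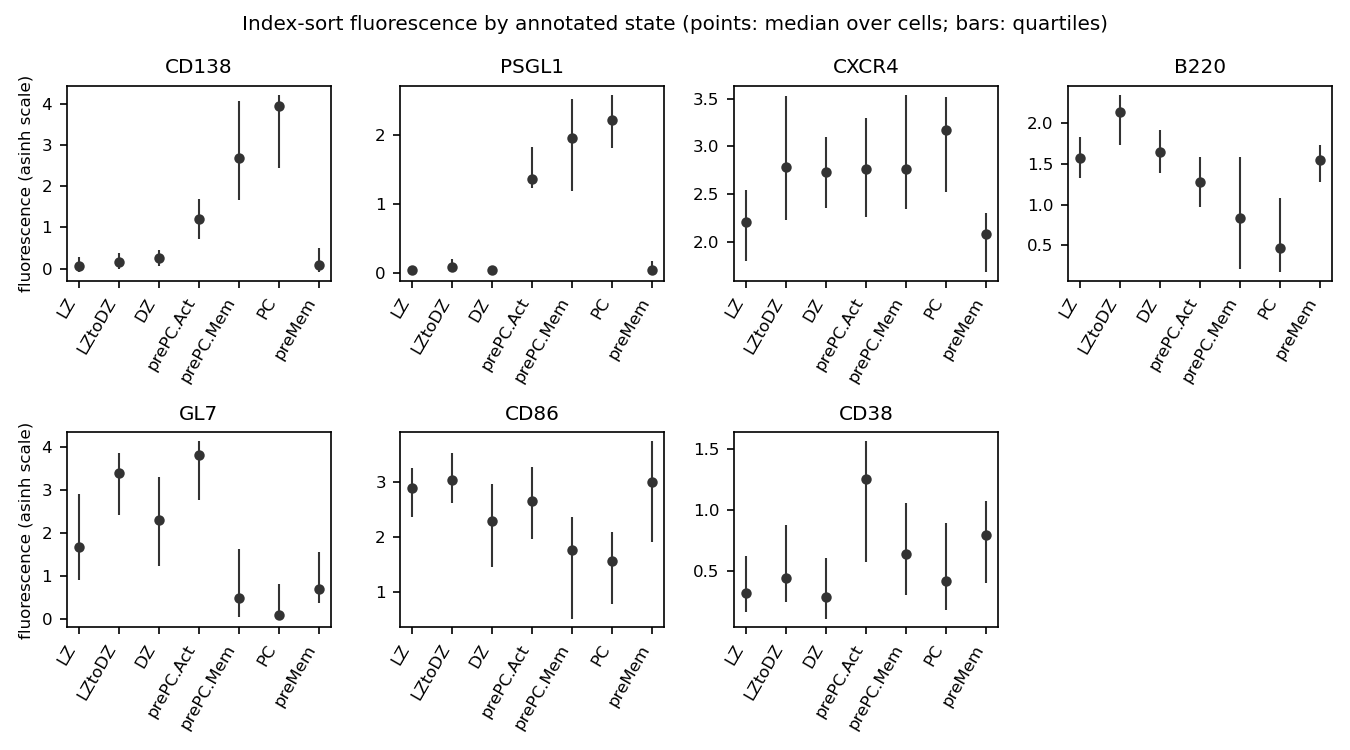
Index-sort fluorescence of 7 markers (inverse hyperbolic sine scale) by annotated state, with the median over cells as a point and the quartiles as a bar. CD138 has a median of 1.21 in activated, 2.69 in memory-like and 3.95 in plasma cells, and GL7 has a median of 3.80 in activated and 0.494 in memory-like cells.

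Heavy chain mutations, the record of time spent in the germinal centre, were compared per plate. The plate medians of mutated bases had a mean of 0.395 (SD 0.567) in plasma cells and 3.45 (SD 0.926) in germinal centre B cells. The difference was -3.05, and plasma cells were lower on 18 of 19 plates (permutation p = 1e-05, the smallest possible, adjusted p = 9.33e-05). Over all cells the medians were 0 and 4. Unmutated heavy chains made up 54.9% (SD 10.3) of plasma cells and 14.7% (SD 11.2) of germinal centre B cells, higher on 19 of 19 plates with the same p. Pre-plasma cells had 56.9% unmutated chains against 18.6% on 7 of 7 plates (exact permutation p = 0.0156, adjusted p = 0.109), which did not pass after adjustment over 28 tests. By state, unmutated chains were 10.3% of 243 dark zone (95% interval 6.77 to 14.8), 17.2% of 151 light zone, 46.4% of 28 activated (27.5 to 66.1), 66.7% of 45 memory-like (51.0 to 80) and 55.4% of 475 plasma cells (50.8 to 59.9). IgM shares did not differ past the threshold, at 19.5% in plasma and 27.1% in germinal centre B cells (12 of 19 plates lower, permutation adjusted p = 0.148). With 1 cell per clone and class the difference was -13.0 percentage points (adjusted p = 0.0272). The share of IGHV1-72, the gene typical of the response to NP, was 12.9% in each class (adjusted p = 0.991). Of 990 cells with a typed heavy chain 227 were IgM, 701 IgG1, IgG2b or IgG2c, 54 IgG3, 4 IgE and 3 IgD.

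**Figure D4:**
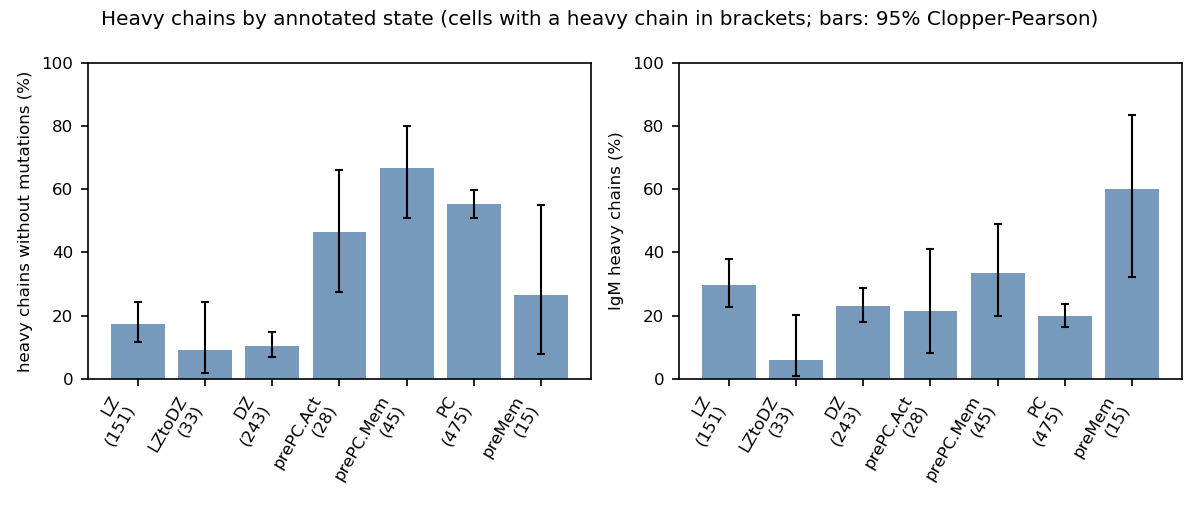
Share of heavy chains without mutations and share of IgM heavy chains by annotated state, in percent of cells with a heavy chain, with Clopper-Pearson intervals at 95%. Unmutated chains range from 9.09% in light-to-dark zone cells to 66.7% in memory-like cells.

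Clones that span classes were counted against shuffles of class labels within each sampleID, and 2 of 4 pairs shared fewer than the shuffled range. Plasma and germinal centre B cells shared 50 clones, against a shuffled median of 88 (78 to 97 in 95% of 10000 shuffles), and pre-plasma and germinal centre B cells shared 8, against 24 (18 to 31). Plasma and pre-plasma cells shared 19 (25, 19 to 31.0), and dark and light zone cells 34 (36, 29 to 42), both inside the shuffled range. The largest clone held 36 cells with IGHV1-22, of which 17 were germinal centre B, 4 pre-plasma and 15 plasma cells. It took in 4 C57BL/6F and 32 C57BL/6M cells, so it is among the clones that span sampleIDs and was counted apart in each above.

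The sampleIDs were compared within each class, 10 plates each for germinal centre B cells. C57BL/6M cells had higher Eif2s3y (4.30 ± 0.75 log2) and Ddx3y (3.94 ± 0.82), both Y-linked, and lower Xist (-5.54 ± 1.08), the RNA of the inactive X chromosome. In plasma cells Eif2s3y at 3.0 ± 0.91 and Ddx3y at 2.72 ± 0.94 log2 did not pass (adjusted p = 0.182 and 0.337), and neither passed in pre-plasma cells. Xist exceeded the Y-linked genes on 8 of 10 C57BL/6F plates and was below them on 10 of 10 C57BL/6M plates. In germinal centre B cells C57BL/6M also had higher Son, a splicing cofactor gene, at 2.09 ± 0.29, the mitochondrial genes Slirp at 1.90 ± 0.32 and Ndufa1 at 1.71 ± 0.31, and the ribosomal protein gene Rps27 at 1.22 ± 0.24 log2. In total 41 of 7423 genes were called in germinal centre B cells, 40 higher in C57BL/6M. With 1 plate left out the count ran from 8 (plate 20) to 70 (plate 11) and moved over 1.5 times for 12 of the 20 plates, and in plasma cells it ran from 30 (plate 20) to 87 (plate 12). In plasma cells 69 of 7216 were called, 63 higher in C57BL/6M, with Son at 1.95 ± 0.26, Ndufa1 at 1.80 ± 0.29 and Ndufc1 at 1.77 ± 0.25 log2, and 23 of the 41 genes were called there too. Immunoglobulin segments differed as well, Ighv1-80 at -5.70 ± 0.54 and Igkv4-59 at 4.21 ± 0.58 log2. In pre-plasma cells 1 of 3674 genes was called, Igkv12-41 at -10.46 ± 1.90 log2, named outside the rule, with 11112 ± 22465 CPM over 5 C57BL/6F pools. Class shares per plate did not differ, with plasma cells at 36.5% (SD 4.23) in C57BL/6M and 30.7% (SD 13.2) in C57BL/6F (permutation adjusted p = 0.599) and an adjusted p of at least 0.475 for every state. The sort gates set these shares, so they describe what was sorted and not the tissue. The class effects themselves differed between sampleIDs in 110 genes for pre-plasma against germinal centre B and 15 for plasma against pre-plasma. Of the 110 genes 93 had the higher effect in C57BL/6M and 17 the lower. The C57BL/6F pre-plasma pools came from plates 2, 3, 4, 6 and 9. Plates 2, 4 and 6 had the lowest median genes per cell (521.5, 471 and 253), and plates 3 and 9 had 1447.5 and 1893. Depth was not tested as a cause. For plasma against germinal centre B the interaction called 0 genes (188 at an unadjusted p under 0.05) and for the zones 0 (115), by edgeR alone.

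On GRCm38 (mm10), from GENCODE vM21, the main regulators lie at chromosome 10, 44437177 to 44528501 (Prdm1), chromosome 13, 30749226 to 30766976 (Irf4), and chromosome 11, 5520659 to 5525893 (Xbp1). Those of the B cell programme lie at chromosome 16, 23965052 to 23988852 (Bcl6), chromosome 4, 44524757 to 44710487 (Pax5) and chromosome 4, 32238804 to 32586108 (Bach2). Sdc1 lies at chromosome 12, 8771323 to 8793715, Jchain at chromosome 5, 88519809 to 88527891, Fkbp11 at chromosome 15, 98724366 to 98728198 and S1pr1 at chromosome 3, 115710433 to 115715072. All are annotated as protein coding.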

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

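The tests of the germinal centre draws, of equal cell numbers, of CD138 in the memory-like state and of plasma cells matched on genes per cell were chosen after the results were seen.

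Of 30 groups of plates tested for a value far from the others, 12 were marked, where chance marks about 1 in 20 groups, or 1.5 here. Plate 6 of C57BL/6F stood apart with 10 cells and 5979 counts, 0% annotated plasma cells, 50% memory-like cells, 20% of cells in the germinal centre gates and 50% in the pre-plasma gate. Plate 14 of C57BL/6M had 63 cells, fewer than the other plates of its sampleID. Plate 16 of C57BL/6M had the most counts, 1.19081e+07 in total with a median of 135176 per cell. Plate 20 of C57BL/6M had a median of 4.94% spike-in counts. Pre-memory cells made up 5.63% of plate 5 of C57BL/6F and 4% of plate 17 of C57BL/6M, the highest shares in each sampleID.

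The class effect differed between sampleIDs by a test of the interaction. For Gcsam the log2 effect of pre-plasma against germinal centre B was 8.38 higher in C57BL/6M, and 110 genes passed that test. Of those genes 93 had the higher effect in C57BL/6M. The C57BL/6F pre-plasma pools included plates 2, 4 and 6, the shallowest by median genes per cell, and depth was not tested as a cause. For Tmem175 the log2 effect of plasma against pre-plasma was 11.13 higher in C57BL/6M, and 15 genes passed.

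More genes were lower than higher in annotated pre-plasma cells against germinal centre B cells, 1263 against 170. Scaling set by immunoglobulin genes is argued against, since 89.0% of called genes were lower without those genes. Fewer and shallower cells in the pre-plasma pools stay open as a cause of the direction, since matched germinal centre B draws gave 99.8% lower among a median of 743.5 called genes. Equal cell numbers left 26 higher and 18 lower genes, 40.9% lower, which this cause also predicts, though on 44 calls. With unequal cell numbers the excess stayed, at 81.8% lower in cells thinned to equal counts and 81.3% in cells with at least 500 genes. The size of the excess stays open too, since the highest draw called 847, or 1228 with cell numbers alone matched, and without estimateDisp the draws called a median of 30 (highest 150) where the real comparison had 894 lower. Of the 1263 lower genes 386 had 0 counts in every pre-plasma pool. Among the same 1263 genes 653 were lower in at least 1 draw, 116 in at least 10 draws and 397 in the gates. A loss of germinal centre transcripts stays open as the biological explanation.

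Memory-like cells had few genes per cell, a median of 376, and inside the plasma cell gate a mean of 322 against 1049 in annotated plasma cells (lower on 9 of 9 plates, exact permutation p = 0.00391). Plasma cells with poor RNA recovery cannot be told apart from a separate state, since 33 cells are few and the difference in CD138, 0.0773 (SD 0.388, exact permutation p = 0.555), was measured inside a gate that CD138 sets. Its percentile 10 was 3.37 there and its percentile 90 in the pre-plasma gate 2.25, so similar CD138 decides nothing. More dead cells in the state stay open. The viability dye was at -0.364 (SD 0.459) relative to plasma cells, lower on 8 of 9 plates (exact permutation p = 0.0391, adjusted p = 0.254). A higher signal had been predicted, but the difference did not pass after adjustment. The dye was among the index-sort values, so cells with a high signal may have been left out by the sort. Over all gates the median mitochondrial share was 2.20% in memory-like and 1.09% in plasma cells. Plasma cells matched on genes per cell still had 740.5 genes, 1.97 times as many, and 2 of 1168 genes were called against them.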

How the results depend on the processing

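Equal cell numbers, the plate block on shared plates, each state alone, the filter on the design, the fit without estimateDisp, the sums with at least 2 cells, the removal of cells with Y-linked counts and all left-out plates and sums were chosen after the results were seen.

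Of 2204 values of named genes under an alternative 2039 kept direction and side of the threshold, 127 were weaker, 15 stronger and 23 reversed. Surface markers kept 180 of 200 and heavy chain features 54 of 56. With camera and an estimated correlation 48 of 88 list results were weaker. Genes changed 2-fold were mostly below what this depth detects, and the cause was not tested for any change below unless fewer plates or cells are named.

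Called genes in annotated pre-plasma against germinal centre B, 1433 as reported, were 470 per sampleID (226 higher, 244 lower), 177 with the plate block, 619 in C57BL/6M, 598 with at least 500 genes, 44 at equal cell numbers, 605 for the activated (253 higher, 352 lower) and 138 for the memory-like state alone (105 higher, 33 lower). Plasma against pre-plasma, 793, gave 519 per sampleID (384 higher, 135 lower), 92 with the plate block, 200 in C57BL/6F, 359 in C57BL/6M, 332 with at least 500 genes and 15 at equal cell numbers, and no filter split 765 higher and 158 lower. Plasma against germinal centre B, 2367, gave 3629 with DESeq2 (1381 higher, 2248 lower) and 1013 in C57BL/6F, and equal cell numbers split 1154 higher and 726 lower.

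Dark against light zone, 77, gave 569 with DESeq2, 133 without filter, 1 per sampleID, 41 with no block, 14 in C57BL/6F, 31 in C57BL/6M, 50 at equal cell numbers (23 higher, 27 lower), 18 in the gates and 187 without estimateDisp. In the gates pre-plasma against germinal centre, 1089, gave 1982 with DESeq2, 529 in C57BL/6F, 495 in C57BL/6M and 1816 without estimateDisp, and splits of 519 higher and 328 lower per sampleID and 539 and 246 at equal cell numbers. Plasma against pre-plasma gates, 1189, gave 2364 with DESeq2 (773 higher, 1591 lower), 729 per sampleID (474 higher, 255 lower), 302 in C57BL/6F, 764 in C57BL/6M and 2075 without estimateDisp, and 411 higher and 798 lower at equal cell numbers. Plasma against germinal centre gates, 2398, gave 3730 with DESeq2, 953 in C57BL/6F (516 higher, 437 lower), 1527 in C57BL/6M and 3622 with the filter on the design, and 1112 higher and 783 lower per sampleID and 938 and 916 at equal cell numbers. The zone gates, 18, gave 135 with DESeq2, 50 without filter, 0 in C57BL/6F, 5 in C57BL/6M, 45 without estimateDisp and 29 with the filter on the design.

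The pre-plasma states, 128, gave 294 with DESeq2 (131 higher, 163 lower) and 176 higher and 11 lower with at least 2 cells per plate. C57BL/6M against C57BL/6F gave 99 with DESeq2 and 97 without estimateDisp in germinal centre B cells (41), 118 and 131 in plasma cells (69), and in pre-plasma cells (1) 31 without filter, 0 without immunoglobulin genes, 0 without plate 6, 0 without cells with Y-linked counts and 7 without estimateDisp.

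With 1 plate left out the calls ran from 2220 to 2557 for plasma and 1261 to 1791 for pre-plasma against germinal centre B, 665 to 1059 for plasma against pre-plasma and 65 to 81 between the zones. Between sampleIDs they ran from 8 to 70 in germinal centre B cells (moved over 1.5 times by plates 1, 3, 4, 8, 9, 10, 11, 14, 15, 16, 19 and 20), 0 to 9 in pre-plasma cells (plates 2, 3, 6, 9, 12, 13, 14 and 19) and 30 to 87 in plasma cells (plates 1, 3, 7, 9, 10, 16, 17, 18, 19 and 20). With 1 sum left out the pre-plasma states gave 64 to 1841, moved over 1.5 times by each of the 4 sums, and the lone sum was assumed to vary like the other state. The gate comparisons were not run with plates left out.

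Reversed log2 values in annotated pre-plasma against germinal centre B were Myc at -10.71 with at least 10 cells, -0.33 with the plate block, -0.033 at equal cell numbers and -2.47 in the memory-like state. Mki67 there was 0.077 with DESeq2, 0.22 per sampleID, 0.99 thinned, 0.031 with at least 500 genes, 0.059 in the activated and 0.76 in the memory-like state, and Jchain -0.56 in the activated state. The gates gave Prdm1 at -0.67 for plasma against pre-plasma, and Cdc20 at -0.18 and Mki67 at -0.41 between the zones. Between the pre-plasma and germinal centre gates Myc was -0.62 in C57BL/6M, -0.28 thinned and -0.095 at equal cell numbers, and Mki67 0.051 per sampleID, 0.0055 in C57BL/6M, 0.061 with at least 500 genes and 0.32 at equal cell numbers. Prdm1 was 0.12 between the plasma and pre-plasma gates in C57BL/6M, and Mki67 3.15 between the pre-plasma states with at least 2 cells. Fry turned light zone (adjusted p = 0.0361) and oxidative phosphorylation (0.00612) in annotated plasma against pre-plasma cells, and the germinal centre share of C57BL/6M minus C57BL/6F was 0.552 points by gate, against -2.02. The cause was not tested.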

Other observations

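The comparison of states in cells thinned to 10000 counts was chosen after the results were seen, and the tests of clones, of Y-linked counts and of splits before.

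Light-to-dark zone cells, which are thought to return to the dark zone after selection, had Myc, the driver of growth after selection, in 47.9% of 48 cells (95% interval 33.3 to 62.8) with each cell thinned to 10000 counts. It was found in 7.95% of 415 dark zone cells (5.54 to 10.99) and 9.02% of 244 light zone cells (5.74 to 13.3), and in 51.7% of 29 activated pre-plasma cells (32.5 to 70.6). Unthinned the shares were 52.1%, 9.29%, 9.71% and 58.6%, and the levels 178, 48.5, 64.1 and 184 CPM. The proliferation marker Mki67 was found in 60.4% of light-to-dark zone cells (45.3 to 74.2; 77.1% unthinned), 36.4% of dark zone cells (31.7 to 41.2; 42.5% unthinned) and 29.1% of light zone cells (23.5 to 35.2; 31.7% unthinned). Intervals cover counting error only, and 37 dark zone and 34 light zone cells were too shallow to enter.

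The 17 pre-memory cells had Pax5 in 41.2% of cells (18.4 to 67.1) thinned to 10000 counts and 266 CPM, against 20.2% and 104 CPM in dark zone cells and 11.5% and 44.1 CPM in light zone cells. The egress receptor gene S1pr1 was found in 17.6% (3.80 to 43.4) at 153 CPM, against 1.64% of light zone cells at 19.5 CPM. Myc was found in 0% of pre-memory cells (0 to 19.5) and Mki67 in 5.88% (0.149 to 28.7). IgM heavy chains made up 60% of 15 pre-memory cells (32.3 to 83.7) and 24.1% of 427 germinal centre B cells (20.1 to 28.5).

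Clones that hold cells of both C57BL/6F and C57BL/6M numbered 25 of 596 and took 181 of 990 cells. Sequence carried between plates stays open. Of 355 pairs across sampleIDs 6.20% were identical, but so were only 10.5% of 841 pairs within 1 sampleID. A carried sequence need match only its source cell, so a low share of pairs cannot decide. An identical sequence in both sampleIDs was held by 7 of the 25 clones. Clone grouping that joins unrelated sequences stays open, since pairs across sampleIDs differed by 1.45 bases more (SD 2.29, 20 clones, permutation p = 0.0113). Cells of 1 sampleID labelled as the other stay open as well, since 50% of the 26 C57BL/6F cells with Y-linked counts, no Xist and a heavy chain sat in such clones, against 9.28% of 97 with Xist (exact p = 1.43e-05). No biological explanation was tested, and a shared receptor in different mice stays possible in principle.

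Other splits of the same pools were counted to see whether chance can be excluded, with the real split among those counted. Only the real split, 1 of 50, reached the 2367 calls of plasma against germinal centre B (highest other 906) and the 77 calls between the zones (highest other 0). If the annotation was made from the same transcripts, its classes were bound to beat random splits. These counts therefore do not exclude chance. For the gates 1 of 30 splits reached the real counts of 1089, 1189, 2398 and 18 (highest other 0 in each). A random assignment of gates within plates is thus argued against, though 30 splits allow no share below 1 in 30. These splits test the spread between plates, and chance between animals cannot be excluded there. The 18 calls between the zone gates were 0 in C57BL/6F and 5 in C57BL/6M alone. Between sampleIDs 1 of 100 reached 41 in germinal centre B cells (highest other 1) and 69 in plasma cells (highest other 2). A random grouping of plates can thus be excluded. The number of mice is not given, so chance between animals and differences in handling cannot be excluded. For annotated pre-plasma cells 1 of 100 reached 1433 against germinal centre B (highest other 2), and 1 of 100 reached 793 below plasma cells (highest other 2). The limit of annotated classes holds for these splits too. These splits mix small and large pools in both arms and leave out pool size, under which germinal centre B draws against germinal centre B cells called 571 to 847 genes. In pre-plasma cells 73 of 100 splits called at least the real 1 gene (highest other 8), so chance cannot be excluded there.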
